A study of Homo sapiens with 4 samples.

How the data were processed

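RNA was sequenced from primary human esophageal fibroblasts of 4 donors treated with 50 ng/ml IL-13 for 24 hours. Per the labels' protocols, cells were grown in smooth muscle cell medium with 2% serum and starved for 16 hours before treatment, and libraries were made from 200 ng RNA by poly(A) selection and a directional kit, which marks the strand of the transcript. Donors, taken from the sample labels, are the replicates, so that p-values of the sign-flip and variance tests measure the spread between donors. Permutation p-values of the strand tests do not. They shuffle pairs of genes, taken as independent, on counts summed over the 4 libraries. The vehicle-treated cells were not analysed here.

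The authors deposited a table of raw counts per gene, without normalization, for the 4 libraries. Bowtie 1.0.0, TopHat 1.4.1 and HTSeq 0.7.1 are named in the submitters' processing notes, with the builds GRCh38 and mm10. The strand setting of the counting and the annotation release are not given in the sources used here. Without their versions, 58039 of 58302 gene identifiers (copies on the Y pseudoautosomal region set aside) were found in GENCODE release 29 (GRCh38), from which coordinates, exon lengths, GC content and overlaps of exons with genes on the other strand were taken. The table has no rows for unassigned reads, so reads outside genes are unknown. Total counts per library ran from 3135065 to 3752310. A count of 0 in all 4 libraries allows up to 0.219 CPM (3 counts of the total), and such floors and the Wilson intervals cover counting error only.

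Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. CPM (counts per 1000000) were computed with TMM library sizes in edgeR, and log2 CPM with a prior count of 2. Values described as CPM of total counts, which are those of genes compared with a neighbour on the other strand, were not scaled by TMM. A gene was called detected at a mean of at least 1 CPM. Before any test 1301 genes were left out: those on the Y chromosome, genes whose level depends on sex, HLA, killer receptor, immunoglobulin and T cell receptor genes, and genes with common deletions, because their values could describe a person. Pseudogenes and copies of mitochondrial sequence were tested but are not reported individually.

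The 24 gene lists, of which 16 are functional and 8 are markers of other cell types, the 20 gene pairs, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The named genes are the detected members of the receptor list and of the IL-13 response list, the 4 members of highest mean CPM of every other list, members of the pairs, the 10 most abundant nuclear genes, and genes called more variable with a mean of at least 10 CPM. A few genes that this rule takes are not reported here. Other list members are named to show a low level and were chosen after their values were seen. The level of a list is the median log2 CPM of its members, with its percentile in each library among 10000 random lists of the same size drawn from genes with any count; percentiles against lists drawn from detected genes are given where stated. Pairs of genes were compared within libraries with an exact two-sided sign-flip test and Benjamini-Hochberg adjustment.

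Variance between donors was tested with limma. The variance of log2 CPM of each detected gene over the 4 libraries was divided by the value of a robust trend on mean log2 CPM, the upper tail of the F distribution gave the p-value, and p-values were adjusted by Benjamini-Hochberg. The variability of a list is the median of this ratio over its detected members, as a percentile among 10000 lists matched on mean log2 CPM in 20 bins. The procedure was tested on simulated counts for 16383 genes at the real means and library sizes of the 4 libraries. It called 74 of 100 genes with an added SD of 1.5 (log2) and 96 of 100 with an added SD of 3. All altered genes had a mean of at least 10 CPM, and 1 dispersion was used for all genes, so the share called among real genes can differ. Of the 16183 other genes in that simulation it called 6, and edgeR's quasi-likelihood deviance called 3. With no gene changed and 1 dispersion for all genes, 20 simulations gave 0 to 1 calls each. The biological coefficient of variation is the square root of edgeR's common dispersion.

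The strand of the counts was examined on 24 pairs of a housekeeping gene and a noncoding gene on the other strand, and, added after that result was seen, on antisense genes with at least 95% of their exon bases inside exons of the principal transcript of a coding gene with at least 100 counts. Housekeeping genes were chosen by name patterns of gene families, which also took in the kinase genes EIF2AK2, EIF2AK3 and EEF2K. In their pairs the noncoding gene was denser (ratios 1.93, 17.8 and 4.84), so the planned share is not one over housekeeping genes alone. Simulated pairs were recovered, with 0 of 200 antisense genes denser when counted on the transcripts' own strand and 197 of 200 on the other. Alternatives included total counts, DESeq2 size factors and upper quartile scaling, other count filters and prior counts, values per kilobase of exon, a mean over list members, other backgrounds and bins, a fit that is not robust, edgeR's quasi-likelihood deviance, DESeq2 dispersions, and leaving out each replicate. Removing a GC trend from each library and leaving out list members that overlap exons of the other strand were added after the data were seen.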

Results

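RNA was measured in primary fibroblasts of the human esophagus, the matrix-producing cells of the esophageal wall, after culture with interleukin-13 (IL-13). IL-13 is a cytokine of type 2 immunity that acts on stromal and epithelial cells through receptors that signal to STAT6. Cells from 4 donors were held without serum for 16 hours and then given 50 ng/ml IL-13 for 24 hours, and poly(A) RNA was sequenced. The 4 libraries, 1 per donor, formed a single group. Vehicle-treated cells were not analysed here, so no response to IL-13 was tested, and the question that these libraries address is which genes the treated cells expressed and how far donors differed. Total counts were 3555733, 3752310, 3135065 and 3269283 in replicates 1 to 4.

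Of 58347 genes in the table, 1301 were left out beforehand. Of the others, 28033 had at least 1 count, and 16383 reached a mean of 1 count per 1000000 (CPM), of which 12747 were protein coding. Each library held between 16079 and 16504 genes at 1 CPM or above. Mitochondrially encoded genes took 2.04% ± 0.32 (SD, n = 4) of counts and ribosomal protein genes 3.65% ± 0.34. The 10 most abundant genes took 14.2% ± 1.57 and the 100 most abundant 33.0% ± 1.52. Pearson's r of log2 CPM across detected genes ran from 0.946 to 0.964 over the 6 pairs of libraries (genes are not independent replicates), and no pair agreed within sampling noise as copies of 1 library would, with a chi-square per gene between 9.26 and 15.9. The biological coefficient of variation between donors was 0.23.

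The values below are counts assigned to a single strand, and genes that share exon bases with a gene on the other strand carried a measurable pattern. A candidate explanation, weighed further on, is counting on the strand opposite to the transcripts. In that case genes without such an overlap would be affected too, their counts being the part of reads that reached the counted strand. Of 176 antisense genes that lie at least 95% inside the principal exons of a coding gene, 170 had more reads per base than that coding gene (96.6%, 95% Wilson interval 92.8 to 98.4), with a median ratio of 5.67. This set was chosen after the planned comparison, in which 11 of 24 noncoding genes opposite a housekeeping gene had more reads per overlapping base than that gene (45.8%, Wilson interval 27.9 to 64.9), with a median ratio of 0.23 (bootstrap interval 0.13 to 2.79). Of nested processed pseudogenes 5 of 11 were denser than the coding gene, with a median ratio of 0.78. Over the 4 libraries the median ratio of the nested antisense genes was 5.71 ± 0.81 (SD, n = 4). The antisense gene AC006064.4 (chromosome 12, 6537794 to 6538370, GRCh38), whose 422 exon bases all lie opposite exons of the glycolytic gene GAPDH, had 5761 ± 1300 CPM of total counts, and GAPDH had 2773 ± 512. VIM-AS1 (chromosome 10, 17214239 to 17229985) had 7630 ± 1028, and VIM, which encodes the intermediate filament protein vimentin, 4033 ± 577. Genes typed as antisense held 8.82% ± 0.85 of all counts. The ratio between genes opposite each other also differed with GC content, with medians of 8.25, 5.99 and 4.56 from the GC-poorest to the GC-richest group of pairs. The scatter of this ratio over the 176 nested antisense genes, taken as the SD on the log2 scale, corresponds to 3.12-fold when a pair of genes is compared. Of the 20 gene pairs compared below, 10 differed by more than that, which as an SD is no bound, so they can still reflect this scatter. The other 10 lay within this scatter, including 6 that had the same direction in all libraries: IL13RA1 with IL13RA2, IL4R with IL13RA1, JAK1 with TYK2, SOCS1 with SOCS3, COL1A1 with COL1A2 and PDGFRA with PDGFRB.

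**Figure D1:**
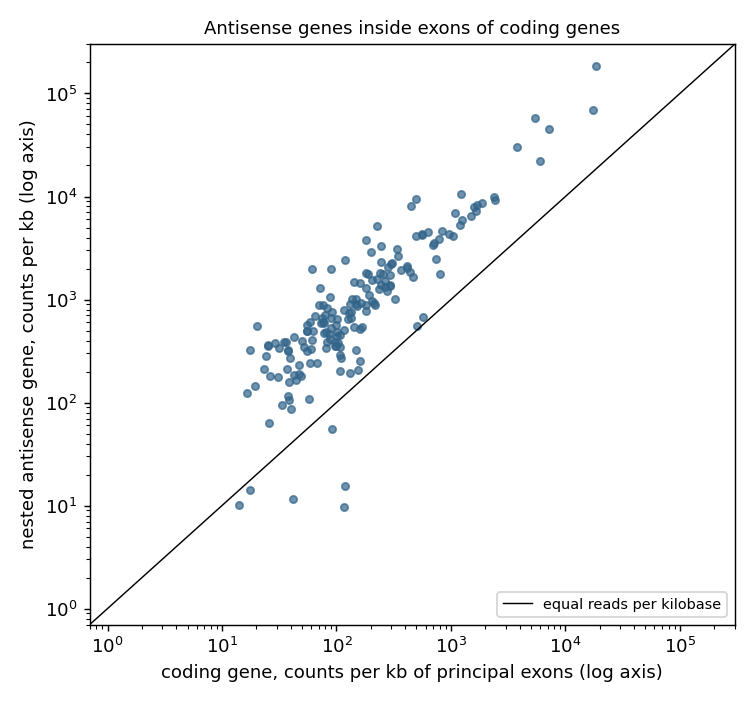
Counts per kilobase, summed over the 4 IL-13 libraries, of 176 antisense genes (vertical, log axis) against the coding gene whose exons contain them (horizontal, log axis), 1 point per pair, with a line of equality. Of the 176 points, 170 lie above the line, at a median ratio of 5.67.

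Matrix genes headed the libraries. Fibronectin (FN1, ENSG00000115414.18; chromosome 2, 215360440 to 215436172) had the highest mean, 22672 CPM ± 7100 (SD, n = 4), and the collagen I gene COL1A1 (ENSG00000108821.13; chromosome 17, 50183289 to 50201632) followed with 21130 ± 5929. The collagen VI genes COL6A1, COL6A2 and COL6A3 had 19799 ± 2647, 14730 ± 1360 and 8581 ± 1736 CPM, and COL3A1 and COL1A2 had 15898 ± 2588 and 15203 ± 3308. QSOX1, a sulfhydryl oxidase, had 7983 ± 1938 CPM, the elongation factor gene EEF2 had 7797 ± 884, and VIM-AS1, whose counts can include reads of VIM, with which it shares 641 exon bases, completed the 10 most abundant nuclear genes. All 15 fibrillar and associated collagens were detected, and together they took 10.2% ± 0.89 of counts. COL1A1 exceeded COL1A2 by 0.46 ± 0.17 on the log2 scale in 4 of 4 libraries. It exceeded COL3A1 in 3 of 4, by 0.38 ± 0.54, which was within the spread, and per kilobase of exon that order was reversed at −0.15.

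All 17 basement membrane genes were detected, led by the laminin and collagen IV genes LAMC1 (1760 ± 381 CPM), COL4A2 (1608 ± 299) and LAMB2 (1111 ± 197) and the perlecan gene HSPG2 (1106 ± 365). All 27 matrix glycoprotein and proteoglycan genes were detected, and after FN1 the highest were SPARC (4976 ± 1626), the fibrillin gene FBN1 (3836 ± 708) and the decorin gene DCN (2576 ± 979). All 20 genes of collagen processing were detected, with P4HB at 1380 ± 413 CPM, the collagen chaperone gene SERPINH1 at 1001 ± 457, PCOLCE at 504 ± 60.1 and LOXL2 at 446 ± 169; 14 of these 20 share exon bases with a gene on the other strand. Of 23 matrix proteases and inhibitors, 17 were detected. The gelatinase gene MMP2 had 3958 ± 1996 CPM, TIMP2 1418 ± 267, SERPINE2 1308 ± 489 and MMP14 1297 ± 90.5, while the collagenase gene MMP1 had a mean of 0.87 ± 1.07, with 0 counts in 2 libraries and up to 2.21 CPM in the others. MMP2 and TIMP1 were above MMP1 in 4 of 4 libraries.

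All 23 contractile genes were detected, led by the nonmuscle myosin gene MYH9 (2402 ± 308 CPM), the tropomyosin gene TPM2 (1146 ± 215), ACTN1 (569 ± 103) and MYL9 (541 ± 157). The smooth muscle actin gene ACTA2, a marker of myofibroblasts, had 277.8 CPM and lay 8.18-fold above MYH11 in 4 of 4 libraries, though both overlap genes on the other strand. In the TGF-beta pathway 21 of 22 genes were detected, with the latent TGF-beta binding proteins LTBP2, LTBP1 and LTBP3 at 692 ± 294, 545 ± 135 and 465 ± 97.7 CPM. TGFB1 was 52.7-fold above TGFB2 (log2 difference 5.72 ± 0.47, 4 of 4 libraries), though TGFB1 shares 215 exon bases with the other strand. Fibroblast lineage markers were all detected, 20 of 20, including the endocytic receptor gene LRP1 at 4372 ± 486 CPM and VIM at 4047.5 ± 685 CPM scaled by TMM. PDGFRA lay below PDGFRB in 4 of 4 libraries (log2 difference −0.84 ± 0.54).

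Genes of both chains of the receptor through which IL-13 signals, IL13RA1 and IL4R, were detected. Of 15 receptor and signalling genes 13 were detected, and the list's median of 5.83 log2 CPM ± 0.13 lay above all 10000 random lists of its size in every library (percentile 99.74 ± 0.13 against detected genes). STAT6, the transcription factor activated by IL-13 and IL-4, had 250 ± 38.3 CPM, JAK1 203 ± 24.7, STAT3 176 ± 28.2, IRS1 148 ± 38.9, PTPN11 82.2 ± 4.34, TYK2 76.3 ± 8.60 and IRS2 56.8 ± 6.11. The receptor chain genes IL4R (ENSG00000077238.13; chromosome 16, 27313668 to 27364778) and IL13RA1 (ENSG00000131724.10; chromosome X, 118727572 to 118794539) had 47.2 ± 4.17 and 31.1 ± 6.48 CPM. IL13RA2, known as a decoy receptor that binds IL-13, had 11.7 ± 8.60 and was 3.07-fold below IL13RA1 (log2 difference 1.62 ± 0.77, 4 of 4 libraries). This fold is not scaled by exon length. The exons span 4372 bases for IL13RA1 and 1626 for IL13RA2, a difference in length that can account for much of it. JAK2 had 11.05 ± 1.88 and JAK3 4.33 ± 2.00 CPM, and JAK1 lay 17.6-fold above JAK2 and 2.64-fold above TYK2 in 4 of 4 libraries. Of these 15 genes 6 share exon bases with a gene on the other strand, among them STAT6 with 128 bases and IL4R with 339, so that their counts can include reads of that gene. IL2RG, the common gamma chain gene that belongs to another IL-4 receptor, and PTPN6, a phosphatase gene, had 0 counts in all libraries, which allows up to 0.219 CPM over the 4 libraries together (3 counts). The mean CPM of IL13RA1 lay 142-fold above this floor, which covers counting error only and is no lower bound on a difference in expression. Over the 20 pairs compared, 16 had the same direction in all 4 libraries (exact p = 0.125, Benjamini-Hochberg adjusted p = 0.156), and no pair could pass a threshold of 0.05, because the smallest p that an exact two-sided sign-flip test on 4 libraries allows is 0.125.

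Genes known from other work to respond to IL-13 or IL-4 were split between expressed and undetected ones. Of 40 genes, 22 reached 1 CPM and 17 reached 10 CPM, and 18 did not, 8 of them with 0 counts in every library. The list's median lay at percentile 52.6 ± 26.9 of random lists drawn from genes with any count, and at 0.03 ± 0.05 of lists drawn from detected genes. The second value is low largely by construction, since the 18 undetected members stayed in the list and the random lists could hold none. The matricellular genes POSTN (periostin) and TNC (tenascin C) had 678 ± 329 and 384 ± 399 CPM (TNC 972 in 1 library and 87.0 to 269 in the others), DPP4 185 ± 40.7, ARG2 165 ± 18.7, the adhesion gene VCAM1 158 ± 66.5, PTGS1 140 ± 30.9 and the monoamine oxidase gene MAOA 102 ± 12.5. The cytokine signalling inhibitors CISH, SOCS1 and SOCS3 had 69.4 ± 9.88, 61.9 ± 7.58 and 30.0 ± 9.70 CPM. SOCS1 was 2.12-fold above SOCS3 in 4 of 4 libraries, while CISH and SOCS1 differed by 0.16 ± 0.18 on the log2 scale, within the spread, and by −1.35 per kilobase of exon. CHI3L1 had 63.5 ± 67.2 CPM, HSD11B1 28.3 ± 12.9, KITLG 24.9 ± 9.37, FLG 9.79 ± 4.79, TSLP 4.19 ± 2.50, TGFB2 3.94 ± 1.46 and EGR2 2.17 ± 1.79. FLG and ARG2 share 704 and 904 exon bases with a gene on the other strand. The esophageal calpain gene CAPN14 had 0.21 CPM and the lipoxygenase gene ALOX15 0.071, at or under the level of 3 counts, and the epithelial gene DSG1 had 0 counts.

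**Figure D2:**
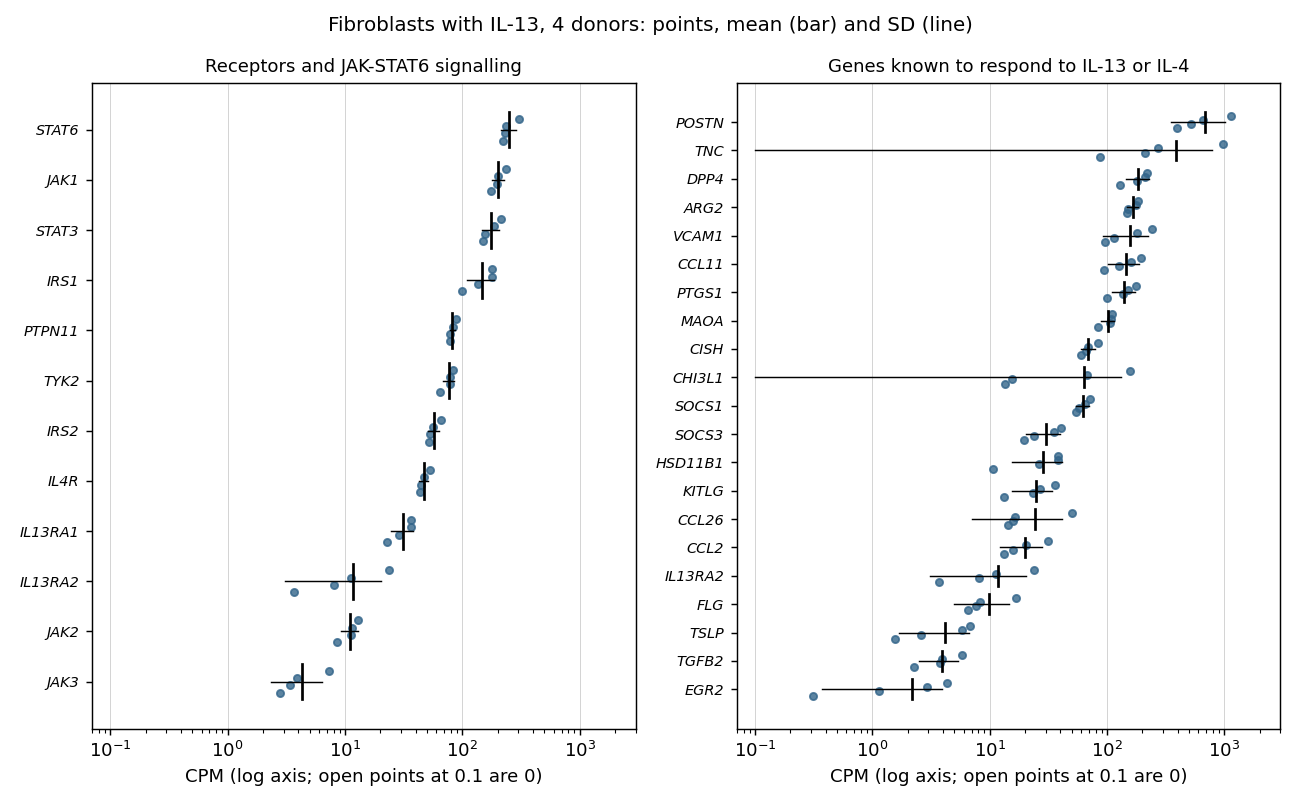
CPM (log axis) of 12 detected receptor and signalling genes (left) and of 21 detected genes known to respond to IL-13 or IL-4 (right) in the 4 donors' fibroblasts with IL-13. Points are libraries, the upright bar is the mean and the line 1 SD, drawn no lower than 0.1. STAT6 has the highest mean on the left, at 250 CPM, and POSTN on the right, at 678 CPM.

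Among 34 chemokine, cytokine and alarmin genes 18 were detected, and the list lay at percentile 17.4 ± 10.5 (0 against detected genes, with its 16 undetected members kept). The eosinophil-attracting eotaxin genes differed in level. CCL11 (ENSG00000172156.3; chromosome 17, 34285668 to 34288334) had 144 ± 42.5 CPM and CCL26 (ENSG00000006606.8; chromosome 7, 75769533 to 75789896) 24.1 ± 17.1, a 6.50-fold difference seen in 4 of 4 libraries (log2 −2.70 ± 1.01). CCL24 had 0.31 ± 0.45 CPM, with 0 counts in 2 libraries, and CCL26 was above it in 4 of 4. CSF1 had 134 ± 48.4 CPM, CXCL12 77.9 ± 77.4 and CCL2 20.2 ± 7.94. CCL2 and CCL26 differed by −0.12 ± 0.49 on the log2 scale, without replicate 4 by 0.057, and per kilobase of exon by −1.615. TSLP and IL33, both epithelial alarmin genes, differed by −0.49 ± 0.87, within the spread. Of 12 TNF family receptor genes 11 were detected, led by TNFRSF21 (440 ± 142 CPM), TNFRSF1A (192 ± 20.8), the lymphotoxin beta receptor gene LTBR (152 ± 10.4) and TNFRSF10B (90.5 ± 20.4). LTBR was 5.45-fold above TNFRSF14, both of which bind LIGHT, in 4 of 4 libraries, though they share 422 and 831 exon bases with genes on the other strand.

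Of 21 cell cycle genes 16 were detected. The cyclin-dependent kinase inhibitor genes CDKN1A and CDKN2A had 614 ± 159 and 96.8 ± 48.0 CPM, CCND1 91.7 ± 36.8 and the replication gene MCM7 44.5 ± 7.87, while the proliferation marker MKI67 had 0.93 ± 0.93. Interferon-stimulated genes were detected in 16 of 19 cases, at percentile 77.2 ± 1.31 (2.47 ± 0.67 against detected genes), and they included IRF1 (24.2 ± 7.62 CPM), IFI6 (15.1 ± 2.34) and BST2 (14.5 ± 9.79). Of 21 stress genes 20 were detected, with the chaperone gene HSPA5 at 675 ± 84.7 CPM, ATF4 at 452 ± 73.7, JUN at 341 ± 91.1 and NQO1 at 157 ± 45.5. Of 16 leukotriene and prostaglandin enzymes 9 were detected. PTGS1, the constitutive cyclooxygenase, led them, followed by LTA4H (56.4 ± 6.76), PTGES3 (50.5 ± 2.21) and PTGES2 (38.2 ± 9.84), and the inducible cyclooxygenase gene PTGS2 had 0.54 ± 0.40.

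Against random lists of equal size drawn from genes with any count, 11 of the 16 functional lists lay above the 95th percentile in every library. These were the receptors and signalling genes, TNF receptors, collagens, basement membrane, matrix glycoproteins, collagen processing, proteases, contractile genes, TGF-beta pathway, fibroblast markers and stress genes. Against lists drawn from detected genes 8 did, without the TNF receptors, proteases and stress genes. Cell cycle genes (percentile 88.4 ± 6.03, and 13.62 ± 11.81 against detected genes), eicosanoid enzymes (64.4 ± 6.03 and 0.69 ± 0.55), interferon-stimulated genes, IL-13 response genes and chemokines were not among them.

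Markers of other cell types were mostly near the detection limit. In every library 6 of 8 marker lists lay below the 50th percentile, those of squamous epithelium (0.04 ± 0.08), endothelium (5.08 ± 5.22), leukocytes and mast cells (0), skeletal muscle (0), glia (11.98 ± 5.11) and adipocytes with mesothelium (0.41 ± 0.56). Members with 0 counts in every library stayed in these lists but could not be drawn into the random ones, which lowers the percentiles. Of 18 squamous markers 3 were detected, the periplakin gene PPL at 133 ± 26.0 CPM and the keratin genes KRT5 and KRT14 at 2.09 ± 4.00 and 1.28 ± 2.20. KRT5 counted as detected through a single library, with 8.09 CPM there and 0 to 0.28 in the others. Endothelial EGFL7 and VWF had 15.7 ± 11.8 and 6.35 ± 4.03 CPM, the macrophage marker CD68 had 6.52 ± 2.73, the muscle gene TNNT1 1.33 ± 1.05, GFAP 4.59 ± 1.98 and PLIN1 1.64 ± 1.029. Smooth muscle and pericyte markers stood higher, at percentiles 90.9 ± 10.1 and 87.7 ± 8.19, and at 48.05 ± 33.6 and 37.74 ± 33.0 against detected genes. SYNPO2 had 265 ± 74.2 CPM, ACTG2 244 ± 80.9, SMTN 118 ± 12.5 and LMOD1 92.8 ± 31.9, and of the pericyte list PDGFRB had 770 ± 57.2, NOTCH3 85.2 ± 82.1, NDUFA4L2 79.95 ± 41.6 and CSPG4 49.8 ± 14.3. Of 13 smooth muscle markers 5 also stand in another list, and of 10 pericyte markers 1 does.

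**Figure D3:**
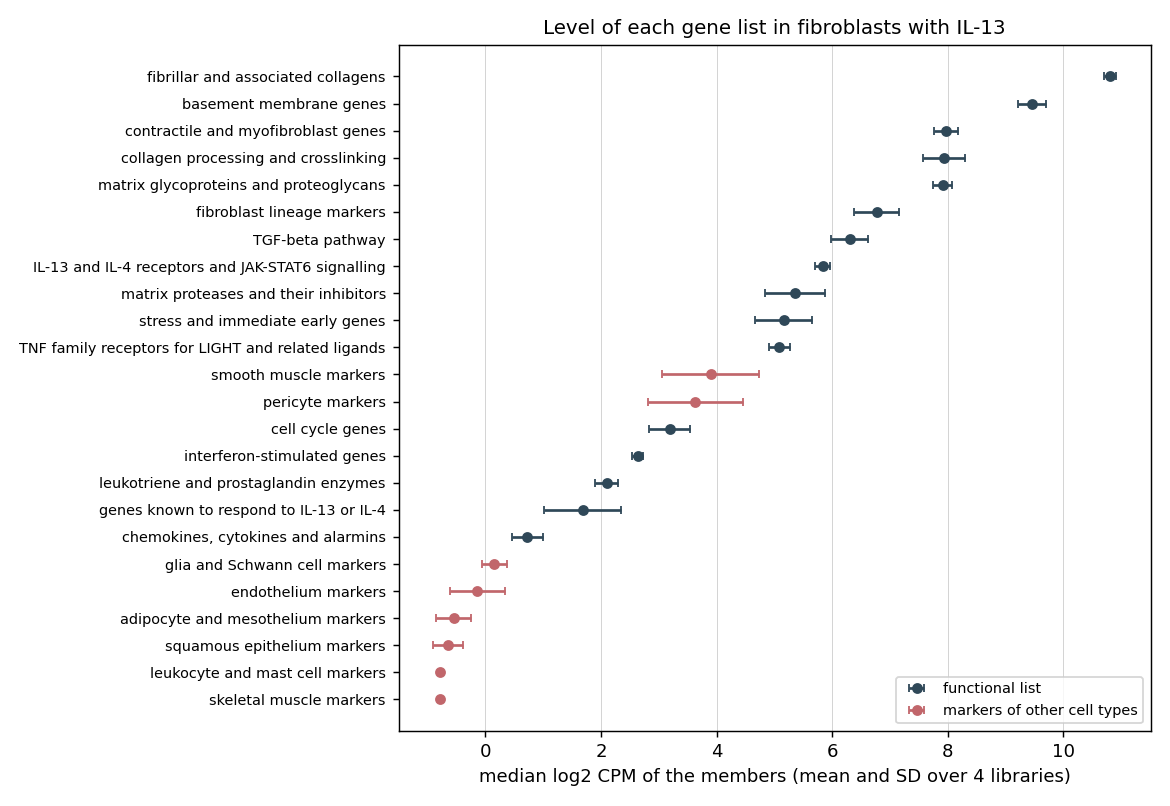
Median log2 CPM of the members of each of 24 gene lists (mean and SD over the 4 IL-13 libraries), functional lists in dark and markers of other cell types in red. Collagens stand highest, and 6 of the 8 marker lists stand lowest.

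Donors differed most in a small set of genes. In limma's test of each gene's variance against the trend, 10 of 16383 genes had more variance between donors than genes of their level at a Benjamini-Hochberg adjusted p under 0.05. In the same test 977 had an unadjusted p under 0.05, where a share of 0.05 of all tested genes would by chance. In 20 simulations of these 16383 genes with 1 dispersion for all and no gene changed, the same test called 0 to 1 genes. These simulations do not cover dispersions that differ between genes of the same level, so they are no full yardstick for the 10 calls. Of the 10 called genes, 4 are pseudogenes or copies of mitochondrial sequence, which share reads with other genes and are not reported individually. The other 6 were AC007938.2 (limma adjusted p = 0.0168), CXCL12 (0.018), MEST (0.018), PCSK2 (0.0357), CHI3L1 (0.0382) and SNHG5 (0.0382). The chemokine gene CXCL12 (ENSG00000107562.16; chromosome 10, 44370165 to 44386493) spanned 9.77 to 174 CPM, a 17.8-fold range. The imprinted gene MEST (chromosome 7, 130486171 to 130506465) spanned 11.6 to 279.8 CPM and AC007938.2, on the other strand of the same locus, 16.96 to 432 CPM. They share exon bases and had the same order over the libraries, so these 2 calls can reflect 1 signal. CHI3L1, which encodes a chitinase-like protein, spanned 13.6 to 157 CPM, and SNHG5, a small nucleolar RNA host gene, 36.9 to 400.5. PCSK2, a prohormone convertase gene, had 0 counts in 1 library and up to 25.3 CPM in the others. The highest library lay 25.9-fold above the floor of 3 counts in a library. The calls rested on few donors and on the settings. All 6 were lost without replicate 1 (2 genes called), with a minimum of 5 CPM (2 genes) and without the robust fit (2 genes), and 42, 7 and 33 genes were called without replicates 2, 3 and 4.

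As groups, 15 of the 19 lists with at least 5 detected members had a higher median variance between donors than 95% of lists matched on expression. The stress genes, matrix glycoproteins, chemokines, IL-13 response genes and pericyte markers lay at the 100th percentile. Receptor and signalling genes lay at percentile 44.8, cell cycle genes at 74.3, contractile genes at 85.1 and collagens at 86.0. The percentiles describe these 4 donors and are not p-values.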

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

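The tests on nested antisense genes, both removals of a trend or of overlapping members, and the GC test on nested pairs were chosen after the result was seen; the tests on housekeeping pairs and on pericyte markers were chosen before.

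Among 123 values checked for a library far from the other 3, 5 stood out, no more than the 1 in 20 expected by chance. CCL26 had 49.8 CPM in 1 library and 14.4 to 16.4 in the others. MAOA had 83.2 CPM in 1 library and 106 to 110.2 in the others. HSPA5 had 801 CPM in 1 library and 621 to 649 in the others. The squamous keratin gene KRT5 had 8.09 CPM in 1 library and 0 to 0.28 in the others. PCSK2 had 0 CPM in 1 library and 20.6 to 25.3 in the others.

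The first pattern is that genes opposite abundant transcripts hold high counts. Counting without regard to strand is excluded by the nested genes, since 97.7% of 176 antisense genes held at least 10 counts where ambiguous reads would have been dropped (of the 4 nested in housekeeping genes, 3 did). For the nested antisense genes, transcription independent of the coding genes is argued against by a Spearman rho of 0.85 across pairs between the reads per base of both genes (bootstrap interval 0.79 to 0.90). The same rho was −0.19 over the 24 housekeeping pairs and −0.54 over the nested processed pseudogenes, so the argument does not extend to these. The planned test of antisense transcription gave a rho of 0.06 (permutation p = 0.77) and left a linked antisense transcription open. A candidate explanation is that reads of this directional library were counted on the strand opposite to the transcripts, which needs the antisense gene to be denser in most pairs: it was in 96.6% of nested antisense genes and 90.6% of nested noncoding genes of all types, and the 8 mitochondrial tRNA genes of the light-strand transcript held 10238 counts against 295 in the 14 of the heavy-strand transcript. The planned test on 24 housekeeping pairs gave 45.8% (Wilson interval 27.9 to 64.9; median ratio 0.23, bootstrap interval 0.13 to 2.79; 79209 counts in the genes and 3811 opposite), which decides nothing by itself, and of the 15 pairs that overlap a principal transcript by at least 100 bases 9 were denser in the opposite gene, a lower share than among the nested genes.

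The second pattern is the order of gene levels in the table. If most reads of a gene went uncounted, its level would follow the share that reached the counted strand, and that share could differ with GC content. In the 17 housekeeping pairs with at least 10 counts in the opposite gene GC content and the gene's own share had a Spearman rho of −0.25 (permutation p = 0.34, interval −0.66 to 0.28), which lies within 0.3 of 0, the bound set beforehand for no trend, though its interval does not. In all 176 nested antisense pairs the rho was 0.44 (permutation p = 2e-05, the smallest that 100000 permutations give), with a higher share in GC-rich genes, the sign opposite to that of the housekeeping pairs. Whether levels of GC-rich genes stand too high against GC-poor genes stays open, and no biological explanation of the order was tested.

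The third pattern is that 15 of 19 lists varied more between donors than genes of the same level. GC trends that differ between libraries cannot account for it as a whole, since 13 of 19 lists stayed above the 95th percentile with the trend removed. Reads of genes with overlapping exons on the other strand cannot either, since 11 of 17 lists stayed above it without overlapping members. Whether a share of reads on the counted strand that differs between libraries contributes was not tested. The median ratio of nested antisense genes was 4.57, 5.67, 6.32 and 6.27 in replicates 1 to 4. For the pericyte markers, a share of pericytes that differs between donors may contribute. The 8 detected markers had a mean pairwise correlation of 0.27 over the libraries, at percentile 96.7 of 2000 lists matched on level. That is just past the 95 set beforehand. The lists were not matched on variability, so this percentile does not decide the question. PDGFRB, also a fibroblast gene, had 770 CPM and NOTCH3 85.2. The smooth muscle markers had a mean pairwise correlation of −0.012, at percentile 55.1. Differences between the donors' cells themselves stay open and were not tested, since donor and library coincide.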

How the results depend on the processing

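The removal of GC trends, the exclusion of members that overlap the other strand and all settings of the nested share were chosen after the data were seen. No paired analysis was possible because there is a single group. The number of functional lists above the 95th percentile, of marker lists below the 50th, of pairs with 1 direction and of variable lists stayed within 1.5 times the reported counts in all settings run. The count of genes more variable than the trend, 10 as reported, did not: it was 29 with total counts, 35 at a minimum of 0.5 CPM, 2 at 5 CPM, 473 with no filter, 5 with 1 CPM required in every library, 2 without the robust fit, 20 with GC trends removed, and 2 (without replicate 1) to 42 (without replicate 2) when replicates were left out, with 33 without replicate 4. Of 16 to 17 alternative settings per gene, CXCL12 lost its call in 3, AC007938.2 and MEST in 4, CHI3L1 in 5, PCSK2 in 6 and SNHG5 in 7. With no filter 28033 genes entered. The mean correlation of libraries, 0.952, was 0.969 with no filter, 0.959 with 1 CPM in every library, 0.938 with a prior count of 0.5 and 0.961 with 5. The biological coefficient of variation was 0.260 by DESeq2 and 0.208 to 0.237 without single replicates. Without overlapping members 192 of 319 list memberships were detected, by construction, and the nested share was 90.6% over all types. Per kilobase of exon the order of CISH and SOCS1 (−1.35) and of COL1A1 and COL3A1 (−0.15) was reversed. This follows from their exon lengths, which are unions over all annotated transcripts and can exceed the length of the main transcript. The number of pairs with 1 direction was 16 per kilobase of exon too, but these need not be the same pairs. Before that scaling IL13RA1 exceeded IL13RA2 by as little as 0.605 on the log2 scale, and its exons are longer (4372 against 1626 bases). CCL2 against CCL26 (−0.12 as reported) ran from −0.32 to 0.057 without single replicates, reversed without replicate 4, and was −1.615 per kilobase of exon. Apart from these, the cause was not tested. With 3135065 to 3752310 counts per library, genes under 0.219 CPM could not be told from 0.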

Other observations

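Some neighbouring genes on opposite strands were singled out because of their values, so they show single cases and no general rule. BEST1, known from the retinal pigment epithelium, had 5324 ± 1446 CPM of total counts (SD, n = 4), above FTH1, the ferritin heavy chain gene on its other strand, with 2175.5 ± 723; they share 1267 exon bases. PCSK7 had 1046 ± 253 CPM of total counts against 489 ± 95.4 for TAGLN, MRNIP 2315 ± 419 against 1084 ± 129 for SQSTM1, and SNX22 1547 ± 312 against 447 ± 57.5 for PPIB. In the mitochondrial genome MT-ND6, on the other strand from MT-ND5 and next to it without overlap, had 2888 ± 514 CPM of total counts and MT-ND5 1157 ± 279.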
